A study of Mus musculus with 18 samples.

How the data were processed

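The deposited file of the series holds expected counts by the authors' labels, with 31.8% of the non-zero values fractional, for 55536 genes in 18 libraries. The values were rounded to whole counts before testing. The sources name FastQC 0.11.8, Trimmomatic, HISAT2, featureCounts of Subread 1.6.2 and edgeR 3.26.4, and the GRCm38 build. The cells were grown in DMEM with 10% FBS, RNA was taken with Trizol and columns, and total RNA libraries (NEBNext Ultra II Directional) were read as paired ends of 76 bases on a NextSeq. The strand setting, the handling of reads with several matches and the annotation release are not given in the sources used here. All 55536 gene IDs were found in GENCODE M21, which gave symbols, types and GRCm38 positions. A count was present for 30522 genes, 118 symbols occurred more than once, and 2 symbols of the lists were absent.

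Genes were kept with filterByExpr, leaving 16322 genes and losing 0.0601% of the counts. Libraries were scaled by TMM. The test was the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group over all 18 libraries, 15 contrasts, and Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. The residual degrees of freedom were 9, the prior degrees of freedom 32.2, the common dispersion 0.000373 and the biological coefficient of variation 1.93%. Responses of different lines were compared by contrasts of differences. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists of each contrast, and again with the correlation estimated from the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

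The 26 lists were NF-κB feedback genes, NF-κB subunits, TNF receptors and adaptors, chemokines, cytokines and growth factors, inflammatory effectors, survival genes, immediate-early genes, MAPK feedback genes, the p38 pathway, interferon genes, SWI/SNF subunits, p53 targets, cell cycle, cholesterol synthesis, fibroblast and matrix genes, positional homeobox genes, histone genes, nuclear long non-coding RNAs, epithelial, endothelial, myeloid, muscle, neural and adipocyte markers, and sex chromosome genes. Btg2 was on both the immediate-early and the p53 list, and Xist on both the nuclear long non-coding RNA and the sex chromosome list. A count "adjusted over the list alone" adjusts the p-values of the members of 1 list together. In comparisons of 2 groups, members with 0 counts in a group were set to their bound for the second median, or left out where the other group had 3 counts or fewer. In differences of responses such members were left out of the second median.

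Named genes followed a rule. Rela and Ikbkb were named in every comparison. Other genes needed an adjusted p under 0.05, a mean of at least 2 CPM in the higher group, no overlap of the 2 groups in CPM where a contrast had 2 groups, and a symbol other than a predicted or clone name. The 10 largest log2 changes in each direction were taken. For TNF in WT the same genes were read in both knock-outs. Some genes that met the rule are not reported here. List examples were taken from the 4 largest changes past the threshold, or from the most abundant members where none passed. The text gives some of these, and members whose call was lost in another fit were often passed over, a choice made after the data were examined. Where a group had 0 counts the fold is given as a lower bound from 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval. These bounds and intervals cover counting error alone.

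The samples, groups, contrasts, lists, rule and first alternatives were fixed before the data were examined. The fit of protein-coding genes alone and the tests of explanations were added after. Columns name the group, and the library code is in no label, so libraries are called a and b and no replicate block could be fitted.

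The pipeline was tested on simulated data made from these counts. Every group was given the mean levels of untreated WT, and changes were planted only in genes of at least 2 CPM there. Recovery of scarcer genes, or of genes low in a knock-out, was not measured. A gene was given the same dispersion in every group, so false calls under unequal spread between groups were not measured either. With 50 genes planted at each fold, the WT 45 min contrast recovered 82% at 1.5-fold, 98% at 2-fold and 100% at 4-fold and 8-fold, with 12 false calls of 202. The p65 KO difference at 45 min recovered 70, 92, 100 and 100%, with 8 false calls of 189. Camera called the planted list (adjusted p = 6.3e-49) and 0 of 20 lists without a planted change. Simulated genes were drawn independently of each other. This check therefore does not cover lists with correlated members, such as the histone genes (estimated correlation 0.726). Pairs of real replicates were checked against counting error, with a chi-square per degree of freedom of 1.13 to 4.27 and a median absolute log2 ratio of 0.043 to 0.064.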

Results

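RNA was measured by paired-end sequencing of 18 libraries from 3 immortalised mouse embryonic fibroblast lines. The lines were wild type (WT), a p65 knock-out (p65 KO, lacking the NF-κB subunit encoded by Rela) and an IKK2 knock-out (IKK2 KO, lacking the IκB kinase subunit encoded by Ikbkb). Each line was left untreated or given 10 ng/ml of tumour necrosis factor alpha (TNF), an inflammatory cytokine that activates NF-κB and MAP kinases, for 45 or 90 min. This made 9 groups of 2 libraries each, named a and b here. Totals ran from 16.7 to 23.5 M counts per library. Between 20146 and 21848 genes had a count in each. Levels below are means in CPM (counts scaled to library size) ± SD (n = 2), and changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test over 16322 genes. For genes named by the fixed rule in a comparison of 2 groups, both libraries of one group lay above both libraries of the other. The p-values measure only the spread between these samples, which may be technical, because the labels do not say whether replicates were separate cultures.

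The knock-out labels were checked against the deleted genes. Rela (gene ID ENSMUSG00000024927, GRCm38 chromosome 19, 5637483 to 5648130) stood at 63.8 ± 0.879 CPM in untreated WT, 5.68 ± 0.606 CPM in untreated p65 KO and 69.7 ± 3.84 CPM in untreated IKK2 KO. The p65 KO level was 8.9% of WT (log2 change −3.49 ± 0.07, adjusted p = 1.4e-36). Ikbkb (ENSMUSG00000031537, chromosome 8, 22659212 to 22706589) was 59.9 ± 0.76 CPM in WT, 42.7 ± 0.0141 CPM in p65 KO and 43.4 ± 0.371 CPM in IKK2 KO. Both knock-outs were lower than WT, with log2 changes of −0.49 ± 0.04 in p65 KO (adjusted p = 2e-13) and −0.46 ± 0.05 in IKK2 KO (adjusted p = 7.2e-12). The IKK2 KO and p65 KO lines differed in Ikbkb by 0.02 ± 0.05 (adjusted p = 0.67). Counts over the whole gene therefore do not check the IKK2 KO label, since RNA outside a deleted part would still be counted. Rela in IKK2 KO stood 0.13 ± 0.04 above WT (adjusted p = 0.0088), a call lost in DESeq2's Wald test (adjusted p = 0.11). TNF raised Rela in WT by 0.56 ± 0.04 at 45 min and 0.77 ± 0.04 at 90 min, and in IKK2 KO by 0.30 ± 0.04 and 0.59 ± 0.04.

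**Figure D1:**
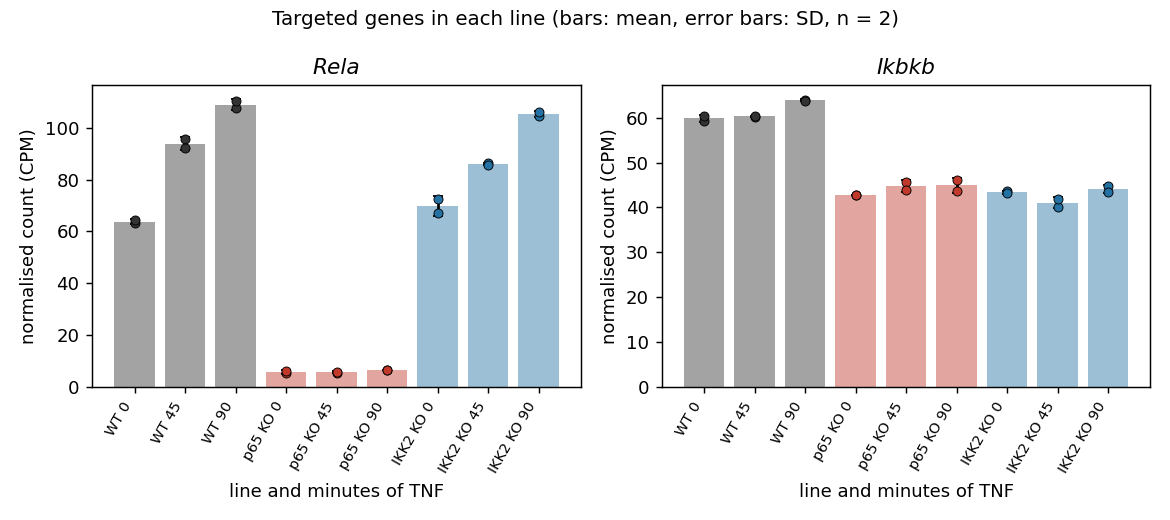
CPM of Rela and Ikbkb in the 9 groups, with bars for the mean of 2 libraries and error bars for the SD. Rela was 5.68 CPM in untreated p65 KO against 63.8 CPM in untreated WT, while Ikbkb was 42.7 and 43.4 CPM in the untreated knock-outs against 59.9 CPM in WT.

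The first comparison asked what 45 min of TNF did in WT fibroblasts. Ccl2, a chemokine that draws monocytes (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), rose from 0.112 ± 0.0153 to 62.4 ± 1.08 CPM (n = 2 each), a log2 change of 9.03 ± 0.14 (adjusted p = 5.4e-39). Its neighbour Ccl7 had 0 counts before and rose at least 40.1-fold. Tnfaip3, which encodes the A20 ubiquitin editor that restrains NF-κB (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657), rose from 8.76 ± 0.311 to 557 ± 7.89 CPM (5.99 ± 0.05). Nfkbia, encoding the inhibitor IκBα (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), rose by 4.60 ± 0.04 to 372 ± 6.44 CPM. Other large rises were those of Cxcl10 (5.47 ± 0.31), the adhesion molecule Vcam1 (4.98 ± 0.08), the transcription factor Irf1 (4.45 ± 0.07), Traf1 (3.95 ± 0.19), Nfkbie (3.90 ± 0.14) and Bcl3 (3.73 ± 0.20). Among genes of at least 2 CPM named by the rule, the largest fall was that of the hyaluronan synthase gene Has2 (ENSMUSG00000022367, chromosome 15, 56665627 to 56694539), from 20.2 ± 0.294 to 3.29 ± 0.457 CPM (−2.60 ± 0.11, adjusted p = 7.4e-23). Dok7 (−2.35 ± 0.34), the transcription factor Atoh8 (−2.17 ± 0.12), Smad9 (−1.83 ± 0.08), Snai1 (−1.71 ± 0.05), Grhl1 (−1.60), Dlx3 (−1.51), Lef1 (−1.43), the phosphatase gene Dusp2 (−1.42 ± 0.10) and the cytokine gene Il11 (−1.36 ± 0.15) also fell.

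By list, 10 of 13 measured NF-κB inhibitors and feedback regulators rose at 45 min in WT and the other 3 were not called (11 rose adjusted over the list alone, median 1.57, camera adjusted p = 5e-21). All 5 NF-κB subunit genes rose, among them Relb (2.85 ± 0.07), Rel (1.51 ± 0.05) and Nfkb2 (1.29 ± 0.04), with a camera adjusted p of 1.4e-16. Of 11 chemokines 8 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 5.9e-12), with a median of 4.61, or 3.06 when members at 0 counts in a group were set to their bound. Of 12 inflammatory effectors 6 rose (8 adjusted over the list alone), including Vcam1, Sele (3.32 ± 0.41) and Tlr2 (3.24 ± 0.10), and Icam1 went from 0 counts to a called rise (median 1.30, camera adjusted p = 3.6e-11). Survival genes had 7 rises, such as Birc3 (2.55 ± 0.14) and Ier3 (1.34 ± 0.04), and 1 fall among 11 (8 and 1 adjusted over the list alone, camera adjusted p = 3.7e-09). Of 26 immediate-early genes 18 rose and 3 fell (19 and 4 adjusted over the list alone, median 0.44, camera adjusted p = 8.9e-16), with Egr1 at 2.36 ± 0.03, Atf3 at 2.24 ± 0.33 and Btg2 at 1.89 ± 0.04. Among 19 p53 targets 12 rose (14 adjusted over the list alone, camera adjusted p = 2.1e-09), for example Fas (2.44 ± 0.12) and Plk2 (1.26 ± 0.03). Cholesterol synthesis genes rose in 9 of 21 cases by small amounts (12 adjusted over the list alone), such as Hmgcs1 (0.37 ± 0.03), with a median of 0.11 and a camera adjusted p of 1.1e-07.

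Smaller or mixed groups followed in WT at 45 min. Of 10 cytokines 5 rose and 2 fell, with Lif, a cytokine of the interleukin-6 family, at 2.36 ± 0.08 (camera adjusted p = 0.031, and adjusted p = 0.091 with an estimated correlation). The interferon list had 4 rises among 22 genes, 5 adjusted over the list alone, with a camera adjusted p of 0.018 and an adjusted p = 0.11 with an estimated correlation. The MAPK feedback list split, with 4 rises, such as Zfp36 (2.61 ± 0.06), and 6 falls, such as Dusp2, among 18 genes (4 and 9 adjusted over the list alone). Its median was −0.08, its mean 0.01 and its camera adjusted p 0.14. Histone genes had 3 falls among 13, with an adjusted p of 0.0015 by camera and an adjusted p = 0.46 with an estimated correlation. The cell cycle list had 2 rises and 1 fall among 25 genes (median 0.04, camera adjusted p = 0.046, adjusted p = 0.46 with an estimated correlation). Camera did not call the p38 pathway (0.28), where the kinase gene Map3k8 rose by 3.09 ± 0.25, or the TNF receptor and adaptor genes (0.61), where Traf2 rose by 0.50 ± 0.09. It did not call SWI/SNF chromatin remodelling subunits (0.52), the fibroblast and matrix list (0.52), positional homeobox genes (0.28) or nuclear long non-coding RNAs (0.28) either. The SWI/SNF subunit genes Pbrm1 (0.02 ± 0.03, adjusted p = 0.85) and Smarcc1 (0.00 ± 0.03, adjusted p = 0.99) were among the most abundant of that list. In total 1988 genes changed, 935 up and 1053 down, of which 293 changed at least 2-fold. DESeq2's Wald test called 1119.

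The second comparison asked what remained of the WT response at 90 min. Ccl2 was still 8.70 ± 0.15 above untreated (49.7 ± 1.75 CPM, adjusted p = 8.6e-37). Cxcl10 (5.49 ± 0.30), Vcam1 (4.94 ± 0.08), Nfkbie (4.04 ± 0.14), Traf1 (3.86 ± 0.19), the growth factor gene Pdgfb (3.73), Tlr2 (3.39 ± 0.10), Bcl3 (3.29 ± 0.21) and Slfn2 (3.14) rose. Lif reached 72.8 ± 0.458 CPM from 8.55 ± 0.313 CPM (3.09 ± 0.07). The endothelin gene Edn1 fell by 1.41 on the log2 scale (SE 0.17, adjusted p = 1.6e-08) and Atoh8 changed by −1.30 ± 0.10. Spry1 (−1.21 ± 0.22), Hey1 (−1.19), Gprc5c (−1.15), Kcnj2 (−1.09) and Mn1 (−1.04) fell. Of 12 inflammatory effectors 11 rose (12 adjusted over the list alone, median 1.89, camera adjusted p = 5.1e-22). All 5 subunit genes rose (median 1.19, camera adjusted p = 3.6e-20), as did 10 of 13 NF-κB feedback genes (median 0.82, camera adjusted p = 1.7e-17). Chemokines had 6 rises and 1 fall among 11 (camera adjusted p = 7.7e-08), cytokines 5 rises among 10 (camera adjusted p = 1e-04) and survival genes 6 rises and 2 falls among 11 (camera adjusted p = 1e-06).

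Of 21 cholesterol genes 12 rose at 90 min in WT (14 adjusted over the list alone, median 0.16, camera adjusted p = 1.3e-08), with Hmgcs1 at 0.40 ± 0.03. MAPK feedback genes had 9 rises, such as Dusp10 (0.50 ± 0.06) and Dusp5 (0.46 ± 0.03), and 3 falls, such as Dusp1 (−0.50 ± 0.06), among 18 (camera adjusted p = 0.0051). Interferon genes had 6 rises and 1 fall among 22 (camera adjusted p = 0.0012), with Irf1 at 1.58 ± 0.10 and the RNA sensor gene Ddx58 at 0.91 ± 0.10. The p53 list had 6 rises, including Fas (2.15 ± 0.13) and Cdkn1a (0.37 ± 0.03), and 1 fall among 19 (camera adjusted p = 0.0086). Positional genes leaned down (median −0.13, camera adjusted p = 0.012), with Hoxa3 at −0.65 ± 0.08 and Tbx15 at −0.31 ± 0.04. Immediate-early genes had 12 rises and 4 falls among 26, with Atf3 at 1.70 ± 0.36, Nr4a3 at 1.16 ± 0.18 and Fos at −0.66 ± 0.13, and a camera adjusted p of 0.0017, but an adjusted p = 0.14 with an estimated correlation. Histone genes had a median of −0.08 (camera adjusted p = 0.0086, adjusted p = 0.57 with an estimated correlation). Camera gave 0.75 for SWI/SNF subunits, 0.14 for the p38 pathway and 0.29 for TNF receptors and adaptors. In all 1521 genes changed, 948 up and 573 down, 138 of them at least 2-fold, and 851 were called by DESeq2's Wald test. The calls of Dok7, Gng8 and Adam4 were lost in DESeq2's Wald test (adjusted p of 0.077, 0.098 and 0.15).

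Between 45 and 90 min in WT, Has2 rebounded from 3.29 to 38.3 ± 2.3 CPM (3.53 ± 0.10, adjusted p = 1.1e-29). The genes Wnt11 (2.12), Vegfa (1.91), Grhl1 (1.85), Sox9 (1.68) and Foxc2 (1.56) also rose, as did Sema7a (1.93), Gja4 (1.93), Hivep3 (1.63) and Gjb2 (1.51). Tnfaip3 fell to 48.5 ± 2.39 CPM (−3.52 ± 0.03, adjusted p = 6.1e-47). Irf1 (−2.87 ± 0.05), Zfp36 (−2.55 ± 0.06), Egr1 (−2.44 ± 0.03), Edn1 (−2.37), Map3k8 (−1.98), Kcnj2 (−1.91), Fos (−1.88 ± 0.11), Nfkbia (−1.86 ± 0.03) and Btg2 (−1.54 ± 0.04) fell. Of 13 NF-κB feedback genes 7 fell and 1 rose (camera adjusted p = 0.00013), and of 19 p53 targets 9 fell and 1 rose (camera adjusted p = 0.00052). Immediate-early genes had 13 falls and 4 rises among 26 (camera adjusted p = 4.7e-07, adjusted p = 0.066 with an estimated correlation). Cell cycle genes had 5 small falls among 25 (median −0.07, camera adjusted p = 0.00052, adjusted p = 0.23 with an estimated correlation). MAPK feedback genes had 10 rises, such as Dusp5 (1.23 ± 0.03), Dusp2 (1.42 ± 0.10) and Dusp6 (0.81 ± 0.04), and 4 falls among 18 (camera adjusted p = 0.058). A total of 2334 genes changed, 1319 up and 1015 down, 243 of them at least 2-fold, and 1283 were called by DESeq2's Wald test.

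**Figure D2:**
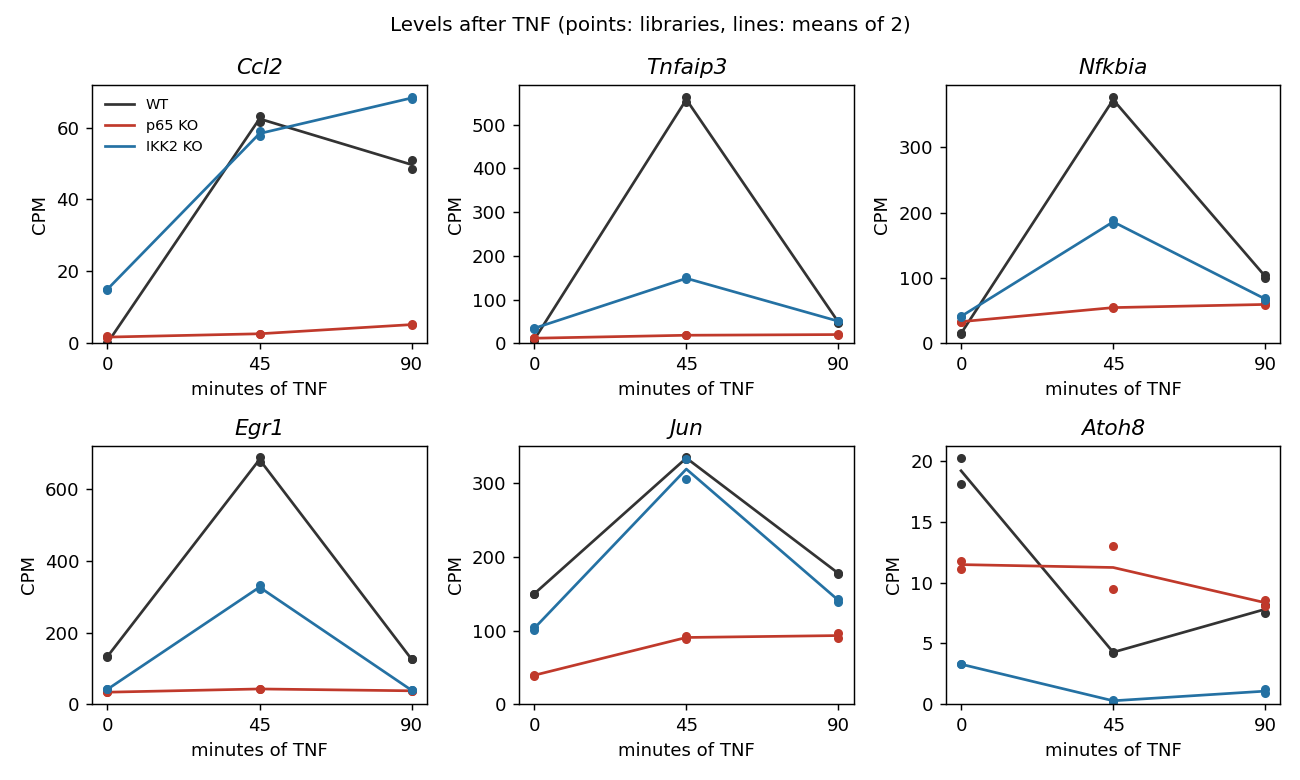
CPM of Ccl2, Tnfaip3, Nfkbia, Egr1, Jun and Atoh8 against minutes of TNF (0, 45 and 90) in the 3 lines, with points for libraries and lines through the means of 2. At 45 min Tnfaip3 stood at 557 CPM in WT, 18.8 CPM in p65 KO and 149 CPM in IKK2 KO.

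The response of the p65 KO line to 45 min of TNF asked what was left in this line. The AP-1 gene Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222) rose from 39.3 ± 1.02 to 90.6 ± 2.51 CPM (1.20 ± 0.05, adjusted p = 7.9e-23). The chemokine gene Cxcl1 rose from 7.81 ± 1.41 to 21 ± 0.437 CPM (1.43 ± 0.10, adjusted p = 9.9e-15). The MAPK phosphatase gene Dusp8 (1.10 ± 0.10), Lif (0.99 ± 0.11), Atf3 (0.97 ± 0.12), Btg2 (0.88 ± 0.16), Junb (0.75 ± 0.04) and Dusp1 (0.74 ± 0.06) rose. So did Nfkbia (0.72 ± 0.05) and Tnfaip3 (0.65 ± 0.07). Falls of the genes named by the rule stayed under 2-fold, as in the small RNA gene Rny3 (−0.96 ± 0.14), Neat1 (−0.47 ± 0.04), Dnm3os (−0.46), Kcnq1ot1 (−0.43 ± 0.05), Xist (−0.41 ± 0.03) and Rprl3 (−0.36). Over all called genes 7 rises and 7 falls reached 2-fold. Among the genes highest after TNF in WT, Ccl2 had 0.59 ± 0.18 here (adjusted p = 0.117), Cxcl10 0.40, Vcam1 0.17, Irf1 −0.12, Traf1 0.28, Nfkbie −0.07 and Bcl3 −0.01, none past the edgeR threshold. Of the genes that fell in WT, Has2 rose here by 0.20 ± 0.04 (adjusted p = 0.00105), while Dok7 (0.13), Atoh8 (−0.01), Smad9 (−0.03) and Snai1 (−0.16) were not called.

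Immediate-early genes led the lists in p65 KO at 45 min, with 12 rises among 26 (16 adjusted over the list alone, median 0.32, camera adjusted p = 8.3e-24). MAPK feedback genes followed with 7 rises among 18 (median 0.20, camera adjusted p = 5.6e-11), such as Zfp36l1 (0.44 ± 0.03). The p53 list had 3 rises among 19, with a camera adjusted p of 1.9e-06. They were those of Btg2, also an immediate-early member, Plk2 (0.51 ± 0.03) and Mdm2 (0.30 ± 0.05). Nfkbia and Tnfaip3 were the 2 risers among 13 NF-κB feedback genes (camera adjusted p = 0.0032). Cxcl1 was the 1 riser among 11 chemokines (3 adjusted over the list alone, camera adjusted p = 8e-04). Ptgs2, encoding cyclooxygenase-2, was the 1 riser among 12 inflammatory effectors (0.54 ± 0.02, camera adjusted p = 0.0082). Survival genes had 2 rises among 11, one of them Ier3 (0.52 ± 0.03), with a camera adjusted p of 0.00087 and an adjusted p = 0.05 with an estimated correlation. Of 7 nuclear long non-coding RNAs 4 fell (median −0.26, or −0.34 without the member at 0 counts in untreated cells), with a camera adjusted p of 3.6e-05 and an adjusted p = 0.061 with an estimated correlation. Intronic features, a sign of unspliced RNA, also sat lower, with a median of −0.39 over 167 features. Camera gave 0.10 for NF-κB subunit genes, 0.76 for the interferon list and 0.068 for SWI/SNF subunits. In this comparison 271 genes changed, 191 up and 80 down, 14 of them at least 2-fold. The count fell to 97 without untreated p65 KO library b and to 156 with DESeq2's Wald test, and rose to 533 when only the 4 libraries compared were fitted. Calls of Gabre (−0.51), Kcnj2 (−0.48), Cavin4 (−0.48) and Slc7a2 (−0.38) were lost without at least 1 library (adjusted p up to 0.22, 0.15, 0.57 and 0.37).

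By 90 min the p65 KO line had changed more genes, 1058 in all, 663 up and 395 down, 51 of them at least 2-fold. Lif reached 23.1 ± 0.657 CPM from 6.08 ± 0.313 CPM (1.93 ± 0.09, adjusted p = 3.6e-20). Cxcl1 (1.74 ± 0.09), Atf3 (1.63 ± 0.11), Ccl2 (1.55 ± 0.15), Cxcl10 (1.43 ± 0.17), Dusp8 (1.33 ± 0.09), Jun (1.25 ± 0.05), the spliceosomal RNA gene Rnu2-10 (1.19), Traf1 (1.07 ± 0.11) and Tcim (1.07) rose. Mitochondrial and small RNA genes were among the falls, with mt-Tv at −1.41 and Rny3 at −0.97. The protein-coding genes Dync2li1 (−0.85) and Mylip (−0.71) fell too. MAPK feedback genes rose in 9 of 18 cases (13 adjusted over the list alone, median 0.42, camera adjusted p = 8.1e-15), with Dusp16 at 0.74 ± 0.05. Immediate-early genes rose in 16 of 26 cases with 1 fall (camera adjusted p = 5.5e-15). All but Rela of the 5 subunit genes rose (camera adjusted p = 6.2e-07), with Relb at 0.40 ± 0.07 and Rel at 0.34 ± 0.06. NF-κB feedback genes had 5 rises among 13 (camera adjusted p = 1.4e-05) and chemokines 5 rises and 1 fall among 11 (camera adjusted p = 9.7e-06). Inflammatory effectors had 2 rises, Ptgs2 (0.79 ± 0.02) and Vcam1 (0.58 ± 0.06), among 12 (camera adjusted p = 0.00028). Survival genes had 5 rises among 11 (camera adjusted p = 5e-07) and p53 targets 6 among 19 (camera adjusted p = 1e-07), with Plk2 at 0.82 ± 0.03.

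Of 19 SWI/SNF subunits, which remodel chromatin, Smarce1 (−0.15 ± 0.03) and Smarcc2 (−0.11 ± 0.03) fell slightly in p65 KO at 90 min, 4 adjusted over the list alone (median −0.06, camera adjusted p = 0.00056). The call of Smarce1 ended without untreated p65 KO library b (adjusted p = 0.1) and that of Smarcc2 in DESeq2's Wald test (adjusted p = 0.15). Nuclear long non-coding RNAs had 4 rises among 7, such as Neat1 (0.57 ± 0.04), with a camera adjusted p of 0.00028 and an adjusted p = 0.092 with an estimated correlation. The median of 167 intronic features was 0.10. Cholesterol genes had 5 rises among 21, with a camera adjusted p of 0.0037 and an adjusted p = 0.23 with an estimated correlation. The mitochondrial ribosomal RNA share fell with time in this line, from 8.66 and 8.92% untreated to 7.11 and 7.1% at 45 min and 5.61 and 6.55% at 90 min, so RNA make-up moved with treatment. The gene count was 452 without untreated p65 KO library b, 572 at most with any of the 4 libraries left out, and 430 with DESeq2's Wald test. Mitochondrial mt-Rnr1 (−0.85) lost its call in a fit of the 4 libraries compared (adjusted p = 0.15), and Mir6236 (−1.60) without the filter on low counts (adjusted p = 0.074). Calls of Abcd2 (−0.83), Irgm1 (−0.70), Bc1 (−0.70) and Igsf9 (−0.66) were lost without at least 1 library (adjusted p up to 0.2, 0.24, 0.15 and 0.35).

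In IKK2 KO, 45 min of TNF asked what was left in that line. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) rose from 41.6 ± 0.35 to 327 ± 9.1 CPM (2.97 ± 0.04, adjusted p = 1.1e-42). Btg2 (2.72 ± 0.10), Cxcl1 (2.63 ± 0.09), Egr2 (2.52 ± 0.10), the RNA-decay factor gene Zfp36 (2.33 ± 0.09), Fos (2.25 ± 0.16), Nfkbia (2.17 ± 0.04), Traf1 (2.14 ± 0.15), Tcim (2.12) and Tnfaip3 (2.10 ± 0.04) rose. Atoh8 (ENSMUSG00000037621, chromosome 6, 72206177 to 72235577) fell from 3.29 ± 0.0183 to 0.285 ± 0.0984 CPM (−3.52 ± 0.37, adjusted p = 7.9e-10). Lfng (−1.50), the BMP target Id2 (−1.49 ± 0.05), Smad6 (−1.45), Dlx2 (−1.44), Ikzf2 (−1.37), Pard6b (−1.21), the activin antagonist gene Fst (−1.20), Foxc2 (−1.18) and Smad9 (−1.17) fell. Of the WT risers, Ccl2 (1.95 ± 0.06, adjusted p = 4.9e-27), Cxcl10 (1.42 ± 0.11) and Irf1 (1.40 ± 0.07) rose, and Nfkbie (0.57) and Bcl3 (0.18) were not called. Of the WT fallers, Has2 (−0.78 ± 0.06) and Snai1 (−1.01) fell.

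Of 26 immediate-early genes 20 rose and 3 fell in IKK2 KO at 45 min (23 and 3 adjusted over the list alone, median 0.81, camera adjusted p = 5.4e-29). Chemokines had 5 rises and 1 fall among 11 (median 1.33, camera adjusted p = 3e-06) and NF-κB feedback genes 3 rises and 1 fall among 13 (camera adjusted p = 0.0018), with Nfkbiz at 1.23 ± 0.08. Subunit genes had 3 rises among 5 (camera adjusted p = 0.0038). Cytokine genes had 3 falls among 10, those of Lif (−0.92 ± 0.12), Csf1 (−0.51 ± 0.03) and Clcf1 (−0.32 ± 0.06), with a camera adjusted p of 0.15. MAPK feedback genes split into 7 rises, such as Dusp8 (1.67 ± 0.11) and Dusp1 (1.61 ± 0.06), and 5 falls, such as Spry1 (−0.38 ± 0.06), among 18 (camera adjusted p = 0.11). Survival genes (4 rises and 1 fall among 11) had a camera adjusted p of 0.0028 and an adjusted p = 0.075 with an estimated correlation. The p53 list (5 rises and 2 falls among 19) had 0.017 and an adjusted p = 0.075 with an estimated correlation. Positional genes had 8 falls among 26, such as Hoxa3 (−0.92 ± 0.16), with a camera adjusted p of 0.013 and an adjusted p = 0.055 with an estimated correlation. Cell cycle genes leaned up (median 0.06) and histone genes down (median −0.09), each with a camera adjusted p of 0.013 and an adjusted p = 0.36 and 0.61 with an estimated correlation. Here 1430 genes changed, 543 up and 887 down, 135 of them at least 2-fold, with 901 without untreated IKK2 KO library a and 802 with DESeq2's Wald test.

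At 90 min in IKK2 KO, Ccl2 rose from 15.1 ± 0.246 to 68.2 ± 0.294 CPM (2.18 ± 0.06, adjusted p = 1e-28). Traf1 (2.11 ± 0.15), Cxcl10 (1.69 ± 0.11), Cxcl1 (1.67 ± 0.10), Ccl7 (1.64 ± 0.15), Nfkbie (1.47 ± 0.24), Lif (1.26 ± 0.09), Relb (1.26 ± 0.07) and Atf3 (1.20 ± 0.11) rose. Atoh8 (−1.60 ± 0.26), Zfp758 (−0.77), Mylip (−0.65) and Smad6 (−0.63) fell. All 5 subunit genes rose (median 0.75, camera adjusted p = 3.4e-17). Immediate-early genes had 13 rises among 26 (16 adjusted over the list alone, camera adjusted p = 6.5e-14), such as Fosl2 (0.56 ± 0.03). Chemokines had 6 rises and 1 fall among 11 (median 1.63, camera adjusted p = 6.4e-11), inflammatory effectors 5 rises among 12 (camera adjusted p = 1.9e-05) and NF-κB feedback genes 4 among 13 (camera adjusted p = 4.4e-05). MAPK feedback genes had 6 rises and 1 fall among 18 (camera adjusted p = 0.00037), and the cytokines Lif and Csf1 (0.42 ± 0.03) rose among 10 (camera adjusted p = 0.0017). Positional genes had 6 falls among 26, 9 adjusted over the list alone, including Hoxb3 (−0.37 ± 0.09, a call lost in DESeq2's Wald test at an adjusted p of 0.078), with a camera adjusted p of 0.00017.

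In IKK2 KO at 90 min 6 other lists passed camera and did not with an estimated correlation. Survival genes (4 rises, such as Birc3 at 1.08 ± 0.12, and 1 fall among 11) had 0.0042 and an adjusted p = 0.075 with an estimated correlation, and p53 targets (4 rises, such as Cdkn1a at 0.78 ± 0.05, and 1 fall among 19) 0.013 and an adjusted p = 0.059 with an estimated correlation. Nuclear long non-coding RNAs had 3 rises among 7, with Neat1 at 0.31 ± 0.03 and Kcnq1ot1 at 0.30 ± 0.04 (camera adjusted p = 0.00024, adjusted p = 0.077 with an estimated correlation). The largest of the 3 was that of Xist (2.32), from 5 counts in untreated IKK2 KO, and carry-over of reads between libraries could give it. Intronic features also leaned up, with a median of 0.13 and 51 of 167 below 0. The p38 pathway had 2 rises among 16 (0.043, adjusted p = 0.26 with an estimated correlation), cholesterol genes 3 among 21 (0.026, adjusted p = 0.36 with an estimated correlation) and histone genes a median of −0.07 (0.011, adjusted p = 0.47 with an estimated correlation). In sum 732 genes changed, 549 up and 183 down, 34 of them at least 2-fold, against 391 without IKK2 KO 90 min library a and 407 with DESeq2's Wald test. Leaving out that library also ended the calls of Rassf7 (−1.02), Fgd4 (−0.81), Tpmt (−0.71) and Ccng2 (−0.68), with adjusted p of 0.19, 0.53, 0.39 and 0.096.

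**Figure D3:**
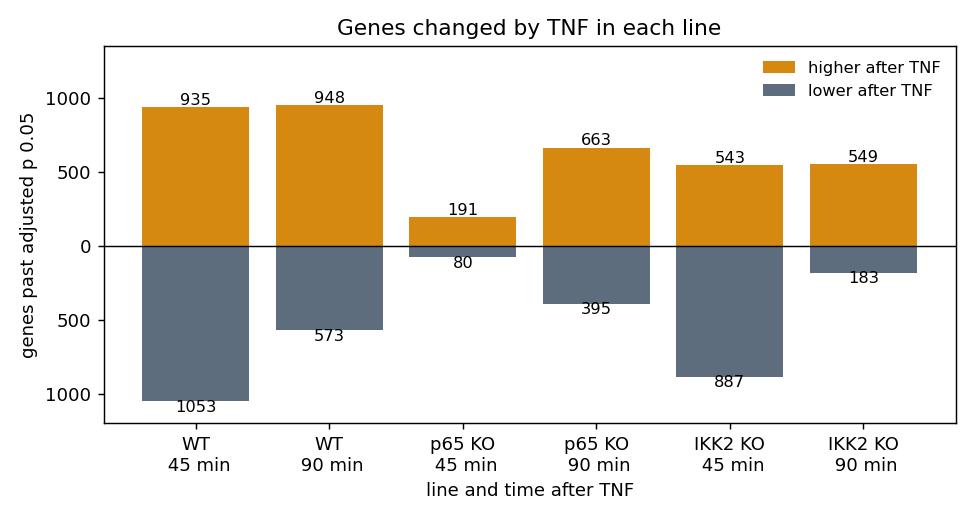
Number of genes higher (above 0) and lower (below 0) after TNF at an adjusted p under 0.05 in each line and time. The 45 min counts were 935 and 1053 in WT, 191 and 80 in p65 KO, and 543 and 887 in IKK2 KO.

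Genes called in one line were shared with another more often than independent draws from the 16322 tested genes would give. At 45 min WT and IKK2 KO shared 227 risers (31.1 expected) and 354 fallers (57.2 expected), and WT and p65 KO shared 45 risers (10.9 expected, one-sided Fisher's exact p = 1.98e-16) and 15 fallers (5.16 expected). At 90 min WT shared 308 risers with IKK2 KO (31.9 expected) and 216 with p65 KO (38.5 expected). Genes are not independent replicates, and abundant genes are easier to call in every line.

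Whether the response itself differed between p65 KO and WT was tested as a difference of log2 changes, p65 KO minus WT. Among genes named by the rule, the largest differences below 0 at 45 min were in Ccl2 (−8.43 ± 0.36, adjusted p = 3.8e-22), Tnfaip3 (−5.34 ± 0.11), Cxcl10 (−5.07 ± 0.44), Vcam1 (−4.81 ± 0.12), Irf1 (−4.58 ± 0.11) and Nfkbie (−3.97 ± 0.23), apart from genes at 3 counts or fewer in a group. Untreated p65 KO had 82 counts of Ccl2 and 84 of Cxcl10, against 5 and 6 in untreated WT. The WT folds of these genes thus began near 0 counts. Of 11 chemokines 7 were higher and 2 lower in untreated p65 KO than in WT (median 2.76, camera adjusted p = 0.086). Above 0 were Has2 (2.81 ± 0.12, adjusted p = 2e-22), Id4 (2.61), Dok7 (2.47), Atoh8 (2.16 ± 0.16), Dusp2 (1.89 ± 0.29), Smad9 (1.80) and Snai1 (1.55), all genes that fell in WT. Below 0 were the differences of 8 of 13 NF-κB feedback genes (9 adjusted over the list alone, median −1.39, camera adjusted p = 8.5e-19) and all 5 subunit genes (median −1.23, camera adjusted p = 5.9e-16). The subunit genes include Rela itself (−0.59 ± 0.13), the gene targeted in this line and left at a low level. Also below were 5 of 11 chemokines (median −3.29, or −2.04 without members at 0 counts in a group, camera adjusted p = 3.3e-09). Inflammatory effectors had 5 differences below 0 and 1 above among 12 (median −0.62, or −0.80 without members at 0 counts, camera adjusted p = 3.7e-06). Survival genes had 5 below and 1 above among 11 (median −0.21, camera adjusted p = 6.5e-06) and p53 targets 4 below among 19 (median −0.16, camera adjusted p = 0.0016). MAPK feedback genes went the other way, with 7 above and 3 below among 18 (median 0.16, camera adjusted p = 0.00013), such as Dusp5 (1.01 ± 0.05) and Dusp1 (0.82 ± 0.08).

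In the 45 min difference between p65 KO and WT 5 further lists passed camera with the preset correlation alone. Immediate-early genes (3 above and 10 below among 26, Egr1 at −2.01 ± 0.06) had 0.0014 and an adjusted p = 0.15 with an estimated correlation. Interferon genes (4 below among 22) had 0.039 and an adjusted p = 0.15 with an estimated correlation, and cholesterol genes (4 below among 21, Hmgcs1 at −0.31 ± 0.05) 3.5e-05 and an adjusted p = 0.11 with an estimated correlation. Nuclear long non-coding RNAs (4 below among 7, Neat1 at −0.49 ± 0.05) had 4e-04 and an adjusted p = 0.11 with an estimated correlation, and histone genes (3 above among 13) 0.0028 and an adjusted p = 0.51 with an estimated correlation. The difference passed for 1156 genes, 567 above 0 and 589 below, 199 of them at least 2-fold, and for 667 with DESeq2's Wald test. The call of Gja4 (1.62) was lost without p65 KO 45 min library b (adjusted p = 0.13).

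At 90 min the p65 KO response still differed from WT in Ccl2 (−7.15 ± 0.36, adjusted p = 1.6e-19), Vcam1 (−4.36 ± 0.11), Cxcl10 (−4.06 ± 0.44), Tlr2 (−3.74 ± 0.17), Nfkbie (−3.47 ± 0.22), Pdgfb (−3.22) and Bcl3 (−2.93 ± 0.26). Above 0 were the differences of Jun (adjusted p = 1.9e-17), which rose more than in WT, Dusp1 (1.15 ± 0.08), Nkx3-2 (1.90) and Usp13 (0.97). Spry1, which fell in WT and was not called in p65 KO, was also above 0 (1.98 ± 0.48, adjusted p = 0.0058), a call lost without p65 KO 90 min library a (adjusted p = 0.081). Of 5 subunit genes all were below 0 (median −0.92, camera adjusted p = 5.3e-18), as were 6 of 13 NF-κB feedback genes (camera adjusted p = 1e-12). The subunit genes again include the targeted gene Rela (−0.59 ± 0.12). Also below were 5 of 12 inflammatory effectors with 1 above (camera adjusted p = 1.2e-10), 5 of 11 chemokines (camera adjusted p = 3.7e-05) and 3 of 10 cytokines (camera adjusted p = 0.001). MAPK feedback genes had 5 above and 2 below among 18 (median 0.11, camera adjusted p = 0.00055), with Dusp8 at 0.94 ± 0.13. Immediate-early genes had 10 above and 3 below among 26 (14 and 3 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.056 with an estimated correlation). Interferon genes (4 below and 1 above among 22, Irf1 at −1.70 ± 0.13) had 0.002 and an adjusted p = 0.055 with an estimated correlation. Survival genes (4 below and 1 above among 11) had 0.014 and an adjusted p = 0.12 with an estimated correlation. The p53 targets leaned up, with 3 above among 19 (median 0.06). They had 0.03 and an adjusted p = 0.097 with an estimated correlation. Cholesterol genes (2 below among 21) had 0.0057 and an adjusted p = 0.23 with an estimated correlation. Nuclear long non-coding RNAs had 0.013 upward and an adjusted p = 0.23 with an estimated correlation, with a median of 0.18 but a mean of −0.08. The difference passed for 880 genes, 313 above and 567 below, 108 of them at least 2-fold. The count was 581 without untreated p65 KO library b and 495 with DESeq2's Wald test.

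The IKK2 KO response differed from WT at 45 min by −7.07 ± 0.24 in Ccl2 (adjusted p = 3.9e-26), −4.85 ± 0.09 in Vcam1, −4.05 ± 0.39 in Cxcl10, −3.90 ± 0.08 in Tnfaip3, −3.33 ± 0.37 in Nfkbie, −3.28 ± 0.15 in Lif, −3.26 in Rnd1 and −3.24 in Pdgfb. In the untreated lines Ccl2 was 0.112 CPM in WT and 15.1 CPM in IKK2 KO, so the smaller fold in IKK2 KO began from a higher level and ended at 58.3 ± 0.918 CPM. Vcam1 likewise began at 126 ± 0.333 CPM in IKK2 KO against 2.68 ± 0.0792 CPM in WT. Differences above 0 were those of Dusp1 (1.69 ± 0.08, adjusted p = 7.7e-20), Gprc5c (1.94 ± 0.42), Has2 (1.82 ± 0.13), Dlx3 (1.81), Lef1 (1.52), Mex3b (1.44), Tcim (1.41) and Dusp2 (1.28 ± 0.13). Has2 fell less than in WT, and Lef1 and Dusp2 fell in WT and were not called in IKK2 KO. Of 26 immediate-early genes 16 were above 0 and 2 below (18 and 2 adjusted over the list alone, median 0.35, camera adjusted p = 1.3e-10), among them Fos (1.03 ± 0.20), Egr2 (0.98 ± 0.12) and Nr4a1 (0.97 ± 0.06). In untreated IKK2 KO 17 of these 26 genes were lower than in WT and 7 higher (median −0.69, camera adjusted p = 0.052). Folds of many members thus began from a lower level in IKK2 KO. MAPK feedback genes had 6 above and 2 below among 18 (median 0.17, camera adjusted p = 0.00084).

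Below 0 in IKK2 KO minus WT at 45 min were 9 of 13 NF-κB feedback genes (camera adjusted p = 6.5e-20), all 5 subunit genes (median −1.12, camera adjusted p = 2e-15), 3 of 12 inflammatory effectors (camera adjusted p = 4e-11). Also below were 5 of 11 survival genes (median −0.22, camera adjusted p = 1.4e-06), 5 of 11 chemokines (camera adjusted p = 5.4e-06) and 2 of 10 cytokines (camera adjusted p = 0.0078). The p53 list had 4 below, such as Plk2 (−0.67 ± 0.04), and 1 above among 19 (camera adjusted p = 0.0027). The 1 above was Btg2 (0.83 ± 0.13), also an immediate-early member. Cholesterol genes (5 below among 21) had 9.9e-05 and an adjusted p = 0.11 with an estimated correlation, and interferon genes (2 below among 22, Irf1 at −3.05 ± 0.11) 0.028 and an adjusted p = 0.13 with an estimated correlation. In this test 794 genes passed, 334 above and 460 below, 109 of them at least 2-fold, and 475 with DESeq2's Wald test. The call of Bcl3 (−3.55 ± 0.93) was lost without untreated IKK2 KO library b (adjusted p = 0.31), and that of Lingo1 (1.33) without IKK2 KO 45 min library a (adjusted p = 0.46).

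At 90 min the IKK2 KO response differed from WT in Ccl2 (−6.52 ± 0.25, adjusted p = 1.4e-23), Vcam1 (−4.67 ± 0.09), Cxcl10 (−3.80 ± 0.40), Trim21 (−2.84), Pdgfb (−2.80), Nfkbie (−2.57 ± 0.35), Sele (−2.55 ± 0.50) and Tlr2 (−2.50 ± 0.16). Above 0 were Edn1 (1.29), Mex3b (0.97), Lfng (0.70), Dusp1 (0.69 ± 0.10) and Id2 (0.63). Below 0 were 6 of 13 NF-κB feedback genes (9 adjusted over the list alone, camera adjusted p = 6.2e-16), 3 of 12 inflammatory effectors (camera adjusted p = 1.2e-14). So were 4 of 5 subunit genes (median −0.51, camera adjusted p = 1.8e-13), 5 of 11 survival genes (median −0.22, camera adjusted p = 1e-05), 4 of 22 interferon genes (camera adjusted p = 5.2e-05) and 4 of 11 chemokines (median −1.27, camera adjusted p = 0.0038). Immediate-early genes (7 above among 26, Ccn2 at 0.56 ± 0.04) had 8e-04 and an adjusted p = 0.15 with an estimated correlation. Cholesterol genes (2 below among 21) had 2e-04 and an adjusted p = 0.15 with an estimated correlation. Cytokines (2 below among 10) had 0.0082 and an adjusted p = 0.05 with an estimated correlation. Nuclear long non-coding RNAs (3 above among 7, Xist among them) had 0.014 and an adjusted p = 0.27 with an estimated correlation. A total of 384 genes passed, 136 above and 248 below, 52 of them at least 2-fold, and 208 with DESeq2's Wald test. The calls of Hs3st3a1 (1.10), Srrm4 (0.89), Spry1 (0.80) and Speg (0.75) were lost in that test (adjusted p of 0.34, 0.26, 0.13 and 0.16), that of Bcl3 (−3.45) without untreated IKK2 KO library b (adjusted p = 0.45), and that of Xist (2.30 ± 0.57) without untreated IKK2 KO library a (adjusted p = 0.42).

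**Figure D4:**
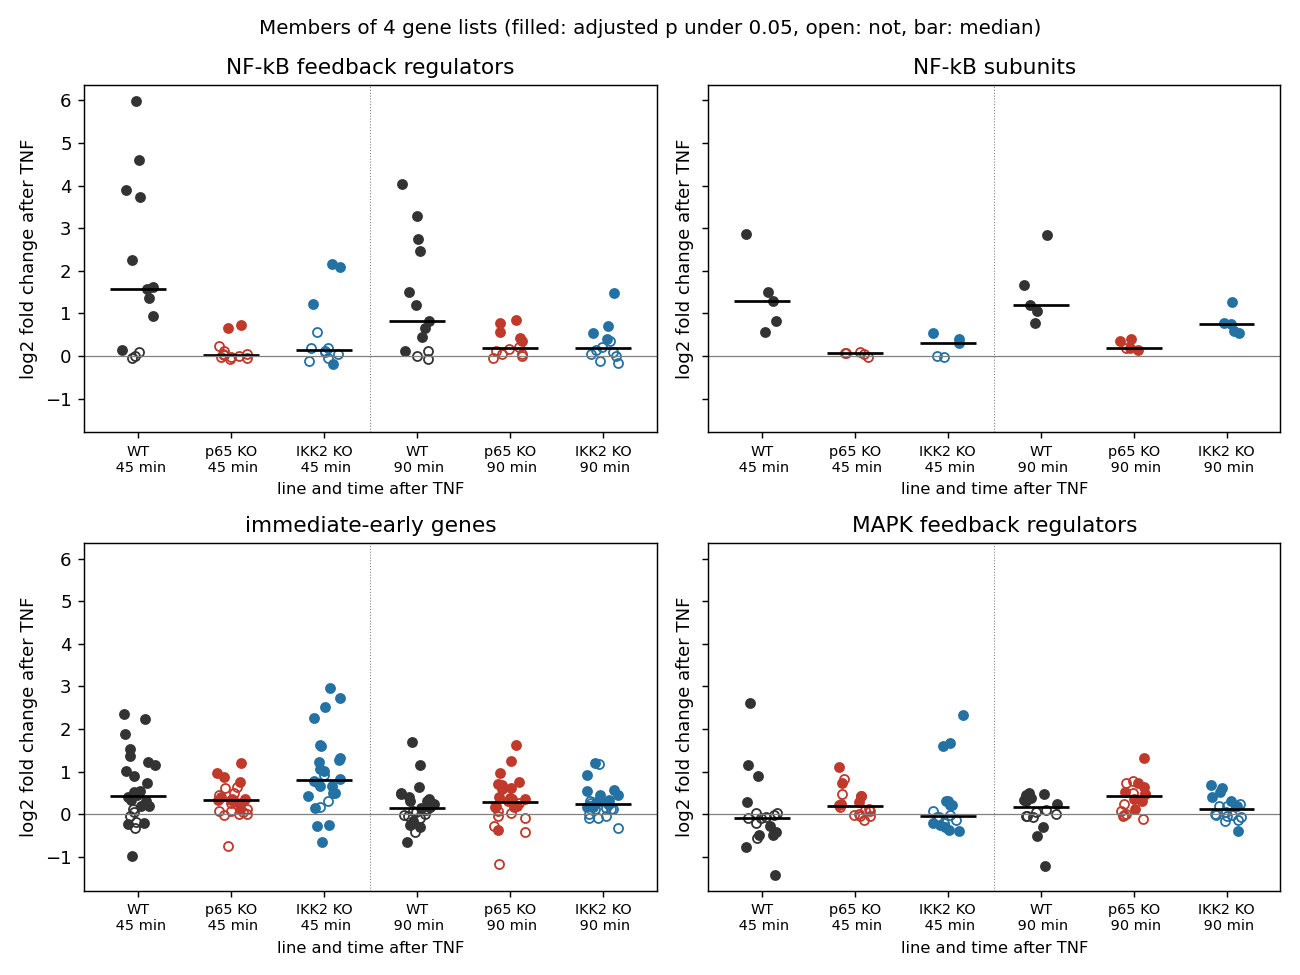
Log2 fold change after TNF of the members of 4 gene lists (NF-κB feedback genes, NF-κB subunits, immediate-early genes and MAPK feedback genes) in each line and time, with filled points for an adjusted p under 0.05 and a bar at the list median. The subunit medians at 90 min were 1.19 in WT, 0.18 in p65 KO and 0.75 in IKK2 KO.

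The 2 knock-out lines were also compared with each other, as IKK2 KO minus p65 KO. At 45 min the response of Egr1 was larger in IKK2 KO by 2.62 ± 0.06 (adjusted p = 4.9e-31), and those of Zfp36 (1.91 ± 0.14), Traf1 (1.87 ± 0.20), Btg2 (1.84 ± 0.21), Fos (1.63 ± 0.30), Irf1 (1.52 ± 0.11) and Tcim (1.47) were larger too. Below 0 were Atoh8 (−3.51 ± 0.39, adjusted p = 7e-09), Lif (−1.92 ± 0.16), Lfng (−1.64), Smad6 (−1.59), Id2 (−1.47), Fst (−1.46), Ikzf2 (−1.35), Dlx2 (−1.34) and Metrnl (−1.22). Of 26 immediate-early genes 16 were above 0 and 3 below (18 and 4 adjusted over the list alone, median 0.43, camera adjusted p = 1.7e-14). NF-κB feedback genes (3 above, among them Tnfaip3 at 1.45 ± 0.09, and 1 below among 13) had 0.019 and an adjusted p = 0.1 with an estimated correlation, and chemokines (3 above among 11) 0.0061 and an adjusted p = 0.08 with an estimated correlation. Nuclear long non-coding RNAs (3 above among 7) had 0.001 and an adjusted p = 0.18 with an estimated correlation. Positional genes (3 below among 26) had 0.037 and an adjusted p = 0.11 with an estimated correlation. Histone genes (2 below among 13) had 0.029 and an adjusted p = 0.64 with an estimated correlation. The difference passed for 965 genes, 366 above and 599 below, 76 of them at least 2-fold, for 615 without untreated p65 KO library b and for 516 with DESeq2's Wald test. Without that library the calls of Egr2 (1.89 ± 0.40, adjusted p = 0.24) ended, and without untreated IKK2 KO library b so did those of Dok7 (−1.34, adjusted p = 0.42) and Rnf122 (1.49, adjusted p = 0.09).

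At 90 min 4 of 5 subunit genes had a larger response in IKK2 KO than in p65 KO (median 0.43, camera adjusted p = 7.9e-13), among them Relb (0.86 ± 0.10) and Nfkb2 (0.57 ± 0.05). Tlr2 (1.23 ± 0.17, adjusted p = 9.8e-06), Traf1 (1.04 ± 0.19), Stx11 (0.89) and Arhgef3 (0.85) were above 0. Jun was below 0 (−0.79 ± 0.06, adjusted p = 2.6e-12), and so was the growth arrest gene Gadd45a (−0.81). Of 18 MAPK feedback genes 3 were below 0 (7 below and 1 above adjusted over the list alone, median −0.16, camera adjusted p = 9.9e-06), including Dusp1 (−0.46 ± 0.10). Chemokines (1 above among 11) had 0.0058 and an adjusted p = 0.052 with an estimated correlation. The p53 targets had 0.045 downward and an adjusted p = 0.15 with an estimated correlation, with a median of −0.13 but a mean of 0.09. The difference passed for 273 genes, 156 above and 117 below, 20 of them at least 2-fold, for 126 without untreated p65 KO library b and for 141 with DESeq2's Wald test. Most of the other genes named by the rule lost their call without at least 1 library, among them Xist (2.12 ± 0.58, adjusted p = 0.57 without untreated IKK2 KO library a), Rnu2-10 (−1.26 ± 0.23, adjusted p = 0.11 without untreated p65 KO library b) and Atoh8 (−1.15, adjusted p = 0.27 without IKK2 KO 90 min library b).

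Before TNF the lines already differed widely. Untreated p65 KO cells had at least 707-fold more Cap2, 696-fold more of the neurotrophic factor Gdnf, 376-fold more Tmem176a, 313-fold more of the transcription factor Tfap2a and 291-fold more Bmp7 than WT, where these had 0 counts. They had at least 1540-fold less Esm1, 783-fold less of the ion channel gene Trpa1, 562-fold less Ebf3 and 545-fold less Inhbb, and Nptx1 was lower by a ratio of 7870 (95% counting interval 1410 to 311000). Of 19 p53 targets 18 were lower and 1 higher (median −2.08, camera adjusted p = 1.4e-06), with the cell cycle inhibitor Cdkn1a at −5.36 ± 0.06, Trp53inp1 at −5.71 ± 0.15 and Fas at −5.00 ± 0.40. Cell cycle genes were higher in 22 of 25 cases, such as Mcm2 (1.48 ± 0.03), and lower in 2, and immediate-early genes lower in 22 of 26 and higher in 3, such as Egr2 (−6.08 ± 0.13), each with a camera adjusted p of 6.3e-06 and an adjusted p = 0.13 with an estimated correlation. Fibroblast and matrix genes were lower in 16 of 21 cases and higher in 3 (0.00042, adjusted p = 0.13 with an estimated correlation), and MAPK feedback genes lower in 13 of 18 and higher in 4 (0.03, adjusted p = 0.13 with an estimated correlation). Histone genes were higher in 12 of 13 cases (0.014, adjusted p = 0.56 with an estimated correlation), and nuclear long non-coding RNAs lower in 6 of 7 (0.014, adjusted p = 0.28 with an estimated correlation), with Neat1 at −2.04 ± 0.04. In total 13196 of 16322 genes differed, 6492 higher and 6704 lower, 5744 of them at least 2-fold.

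Untreated IKK2 KO cells had at least 397-fold more of the fibroblast surface gene Thy1, 388-fold more of the mechanosensitive channel gene Piezo2, 349-fold more Plce1, 338-fold more En1 and 271-fold more Gas6 than WT. They had at least 1620-fold less Cdh13, 1430-fold less of the fibrillin gene Fbn2, 1080-fold less Perp and 733-fold less Arhgap36, and Xist, the X-inactivation transcript, was at 0.155 ± 0.219 CPM against 1366 ± 20 CPM (−13.11 ± 0.09). Of 19 p53 targets 16 were lower and 2 higher (median −1.93, camera adjusted p = 1e-05), with Eda2r at −5.48 ± 0.11. Cholesterol genes were higher in 20 of 21 cases (median 0.94, camera adjusted p = 3.7e-08, adjusted p = 0.1 with an estimated correlation), such as Fdps (1.78 ± 0.07), and cell cycle genes in 18 of 25 with 3 lower (0.0033, adjusted p = 0.31 with an estimated correlation). Subunit genes were higher in 4 of 5 cases, with Relb at 1.27 ± 0.10, and camera gave 0.21 for the list. In total 12122 genes differed, 5860 higher and 6262 lower, 4508 of them at least 2-fold. Each genotype was a single line, so genotype and line cannot be separated in any comparison between lines, of untreated cells or of responses to TNF. With an estimated correlation the camera calls that held were those given above without such a value.

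Lists of other cell types were read in untreated cells to see what the cultures expressed. Of 24 fibroblast and matrix symbols 18 reached 1 CPM in WT, 19 in p65 KO and 20 in IKK2 KO, the most abundant being Fn1 in WT (5080 CPM) and Vim in the knock-outs (2300 and 4350 CPM). Epithelial markers reached 1 CPM for 2 of 12 symbols in IKK2 KO, with Ocln at 6.78 CPM. The most abundant epithelial marker was Krt19 in WT (0.128 CPM) and Krt8 in p65 KO (0.478 CPM). Endothelial markers stayed under 1 CPM, the most abundant being Esam in WT (0.413 CPM) and Cdh5 in the knock-outs (0.197 and 0.818 CPM). Of 11 myeloid markers Cd68 alone passed 1 CPM, at 1.54 in WT and 1.15 in IKK2 KO. Of 10 muscle markers Acta1 reached 2.32 CPM in WT and Mylpf 1.06 CPM in p65 KO. Neural markers reached 1 CPM for 5 of 10 symbols in WT, 5 in p65 KO and 4 in IKK2 KO, with Nes at 431 CPM in WT and Sox2 at 163 CPM in p65 KO. The adipocyte marker Cebpa was 6.26 CPM in WT, 0.457 CPM in p65 KO and 0.604 CPM in IKK2 KO, and of the 5 sex chromosome symbols Xist passed 1 CPM in WT and p65 KO. The ribosomal RNA repeat gene Gm26917 took 9.95 to 10.97% of counts in WT, 1.29 to 2.12% in p65 KO and 13.7 to 14.95% in IKK2 KO, so the lines also differed in leftover ribosomal RNA. Of the positional genes Tbx15 was highest in WT (88.8 CPM) and p65 KO (136 CPM) and Hoxb9 in IKK2 KO (69.6 CPM). After 45 min of TNF in WT camera gave 0.94 for epithelial, 0.94 for endothelial, 0.99 for myeloid, 0.24 for muscle, 0.28 for neural, 0.61 for adipocyte and 0.99 for sex chromosome lists. It called none of these 7 lists in any of the 15 comparisons. In that order they held 2, 2, 2, 3, 6, 1 and 1 measured genes after the filter, so a missing call says little. In untreated IKK2 KO camera gave 0.23 for the sex chromosome list, though its only measured member Xist was called at −13.11.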

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

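The differences of responses below come from contrasts chosen before the result was seen, and all tests of explanations in this closing section were chosen after it.

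The results in this part stand out because a test of the difference of responses between lines passed. In p65 KO minus WT at 45 min 1156 genes and 12 lists passed, 7 of the lists also with an estimated correlation. Medians without members at 0 counts were −1.39 for NF-κB feedback genes, −1.23 for subunit genes, −2.04 for chemokines, −0.80 for inflammatory effectors, −0.21 for survival genes, 0.16 for MAPK feedback genes and −0.16 for p53 targets. Among genes named by the rule Has2 was at 2.81 and Ccl2 at −8.43. At 90 min 880 genes and 12 lists passed, 6 of the lists also with an estimated correlation. Medians were −0.73 for NF-κB feedback genes, −0.92 for subunit genes, −1.19 for chemokines, −0.32 for cytokines, −0.45 for inflammatory effectors and 0.11 for MAPK feedback genes. Ccl2 was at −7.15. Spry1 was at 1.98 and lost its call without p65 KO 90 min library a (adjusted p = 0.081).

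In IKK2 KO minus WT at 45 min 794 genes and 11 lists passed, 9 of the lists also with an estimated correlation. Medians were −1.05 for NF-κB feedback genes, −1.12 for subunit genes, −1.75 for chemokines, −0.09 for cytokines, −1.23 for inflammatory effectors, −0.22 for survival genes, 0.35 for immediate-early genes, 0.17 for MAPK feedback genes and −0.17 for p53 targets. Gprc5c was at 1.94 and Ccl2 at −7.07. At 90 min 384 genes and 10 lists passed, 6 of the lists also with an estimated correlation. Medians were −0.64 for NF-κB feedback genes, −0.51 for subunit genes, −1.27 for chemokines, −1.18 for inflammatory effectors, −0.22 for survival genes and −0.41 for interferon genes. Ccl2 was at −6.52. Xist was at 2.30, from 5 counts in untreated IKK2 KO, and lost its call without untreated library a (1.27, adjusted p = 0.42).

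In IKK2 KO minus p65 KO at 45 min 965 genes and 6 lists passed, 1 of the lists also with an estimated correlation. This was the immediate-early list, with a median of 0.43. Egr1 was at 2.62 and Atoh8 at −3.51. At 90 min 273 genes and 4 lists passed, 2 of the lists also with an estimated correlation. Medians were 0.43 for subunit genes and −0.16 for MAPK feedback genes. Xist was at 2.12 and lost its call without untreated IKK2 KO library a (1.10, adjusted p = 0.57). Rnu2-10 was at −1.26 and lost its call without untreated p65 KO library b (adjusted p = 0.11).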

How the results depend on the processing

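The settings below were planned except the fit of protein-coding genes alone, which was added after seeing the data, and all tests of explanations were chosen after the result was seen.

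Genes changed at least 2-fold numbered 293 and 138 in WT at 45 and 90 min, 14 and 51 in p65 KO, 135 and 34 in IKK2 KO, 243 in WT between 45 and 90 min, 5744 and 4508 in untreated p65 KO and IKK2 KO, 199 and 108 in p65 KO minus WT, 109 and 52 in IKK2 KO minus WT, and 76 and 20 in IKK2 KO minus p65 KO. DESeq2's Wald test (version 1.42.0) called 1119, 851, 156, 430, 802, 407 and 1283 genes in the first 7 of these, and 667, 495, 475, 208, 516 and 141 in the 6 differences. Fitting only the 4 libraries compared gave 533 genes in p65 KO at 45 min.

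Leaving out 1 library gave 1446 to 1559 genes in WT at 45 min, 1016 to 1213 in WT at 90 min and 1626 to 1794 between them. It gave 97 to 186 and 452 to 572 in p65 KO, 901 to 1179 and 391 to 512 in IKK2 KO, 12595 to 12731 and 11219 to 11562 in the untreated lines. The differences ran from 853 to 999 and 581 to 777 in p65 KO minus WT, 599 to 711 and 260 to 336 in IKK2 KO minus WT, and 615 to 881 and 126 to 195 between the knock-outs.

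With an estimated correlation camera called 4 lists in IKK2 KO at 45 min and 8 at 90 min, 2 in WT between 45 and 90 min, 1 in each untreated knock-out, 7 and 6 in p65 KO minus WT, 6 in IKK2 KO minus WT at 90 min, and 1 and 2 in IKK2 KO minus p65 KO. The fry test called 12 lists in WT between the times, 24 in each untreated knock-out and 8 in IKK2 KO minus p65 KO at 90 min. Unlike camera, fry asks whether members change at all, not whether they change more than other genes. In untreated p65 KO and IKK2 KO 13196 and 12122 of 16322 genes differed from WT. Most lists would pass fry there, so the 24 say little about these lists.

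Of 1224 pairs of gene and comparison 1000 were called, and none of these changed sign in a setting in which it had a value. Changes of sign were not scored for the other pairs. Of the 1224 pairs 1091 had a value in DESeq2's Wald test, 1149 with the stricter filter and 1156 in the fit of the libraries compared. A total of 243 of 300 called pairs named by the rule kept their call in every fit in which they had a value. The protein-coding fit (12315 genes) called 1812 genes in WT at 45 min. No paired analysis was possible because the library codes are in no label, and for the same reason the replicate block could not be fitted and was not run.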

Other observations

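The list of BMP and SMAD targets and all tests in this part were chosen after the result was seen.

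Targets of bone morphogenetic protein signalling were read after several were seen among the falls. Of 13 measured genes (Id1, Id2, Id3, Id4, Smad6, Smad7, Smad9, Atoh8, Bambi, Msx1, Dlx2, Dlx3 and Hey1) 12 fell in WT at 45 min (median −1.03), and 10 rose again between 45 and 90 min (median 0.65). Id1 went from 153 ± 1.85 to 82.9 ± 2.04 CPM and back to 130 ± 2.68 CPM in WT. In IKK2 KO 9 fell and 1 rose at 45 min (median −1.07), with Id2 from 111 ± 0.804 to 39.6 ± 4.27 CPM. In p65 KO 1 rose and the others were not called (median −0.02), and at 90 min 6 fell (median −0.19). Msx1 had 0 counts in both knock-outs and enters their medians with a change of 0. The members were picked after several were seen to fall, so no test of the list is given.

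Levels too low in p65 KO could hide a fall. For 9 members the test of the difference between p65 KO and WT passed, which argues against that for these 9 alone. The list was picked after several members fell in WT. Msx1 (0 CPM) and Dlx3 (0.282 CPM) also fell in WT but were low in untreated p65 KO, so for them low levels stay open. Hey1, which did not pass either, stood at 15.3 CPM there. A general loss of short-lived transcripts could lower the BMP and SMAD targets and stays open. The immediate-early list, which is short-lived, had a median of 0.44 in WT at 45 min, but TNF induces it, and this would hide a loss. Loss of p65 is a possible cause, and with 1 line of that genotype it cannot be told apart from another difference of the line.

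Genes with at least 20 CPM in untreated WT and 0 counts in an untreated knock-out were read in its treated libraries. By this choice the untreated libraries are at 0, so the values do not tie traces to treatment, and Xist, not chosen this way, had 5 counts in untreated IKK2 KO library b. The share of the WT level of 10 such genes in p65 KO was 0 and 0.0645% at 45 min and 0.0104 and 0.284% at 90 min, mostly from 1 library. That of 18 such genes in IKK2 KO was 0.012 and 0.011% at 45 min and 0.0588 and 0.0913% at 90 min. Carry-over of reads could give the Xist counts in IKK2 KO, with a ratio of 0.746. Syk had 28 counts in the 4 treated p65 KO libraries, against 2.6 expected from that share (ratio 10.8). However, Syk was read after it stood among the differences above 0 in p65 KO minus WT (2.67 ± 0.83 at 45 min). It also had 2 counts in untreated p65 KO, where the other genes were chosen at 0. The ratio therefore does not exclude carry-over for Syk.

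Some nuclear long non-coding RNAs in p65 KO fell at 45 min and rose at 90 min (4 of 7 called each time, medians −0.34 and 0.25 over the 6 with counts in untreated cells). Neither list call held with an estimated correlation (adjusted p = 0.061 and 0.092). A different share of nuclear or unspliced RNA in the libraries may account for this, since intronic features had a median of −0.39 at 45 min, with 149 of 167 below 0. The 2 kinds of RNA did not always move together. In IKK2 KO at 45 min intronic features had a median of −0.15, with 114 of 167 below 0, and the nuclear long non-coding RNAs 0.08. A bias by gene length is argued against by a median of −0.02 over 2104 coding genes of more than 8000 exonic bases.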
